A study of Mus musculus with 12 samples.

How the data were processed

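RNA was measured in 12 libraries from C57BL/6 mouse midbrain, in 4 groups of 3. The mice had received saline or preformed fibrils of G51D α-synuclein, a variant linked to familial Parkinson's disease, on both sides of the substantia nigra. The fibril dose was 20 µg at 5 µg/µL, and tissue was taken 7 or 12 weeks later, per the labels. Cells positive for hKO1, a fluorescent reporter of dopaminergic neurons in this study, were sorted from dissected midbrain into TRIzol LS. RNA was purified with a Direct-zol microprep kit and amplified with the SMARTer Ultra-Low RNA kit, per the labels' protocols.

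The authors aligned reads with TopHat2 2.0.13 and Bowtie2 2.2.3 and estimated expression with Cufflinks 2.2.1, per the submitters' processing notes. Estimated counts and FPKM were deposited by the authors for 24346 genes, with 1 value of each per library, and all genes had an OK status. The deposited estimated counts are not raw: in each library 98.8% to 98.9% of values were whole multiples, within a tolerance of 0.02 fragments, of 1 step between 0.685 and 1.30. That step is the factor by which the authors scaled the library, per the values in the deposited files. Dividing by it gave 2506730 to 5533321 assigned fragments per library. With 3 libraries per group the median standard error of a log2 fold was 0.53 over all genes tested and 0.26 over genes above 100 CPM. Nothing in the labels says that replicates are separate animals, so p-values measure the spread between samples. The genome build is not given in the sources used here. Of the gene names, 95.7% were found in GENCODE release M21 for mm10 (GRCm38), and 61.2% of these had both ends within 1000 bases, so coordinates are given as in the deposited files and read as mm10. Starts were moved by 1 base to count from 1. No mitochondrially encoded genes are in the tables used here, and 1313 models are small RNAs shorter than 200 bases.

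The deposited counts were rounded to whole numbers and tested in edgeR 4.0.16 under R 4.3.3. Genes passed filterByExpr with its default settings, which left 17380. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, with 8 residual degrees of freedom and a common biological coefficient of variation of 46.6%. Adjusted p-values are Benjamini-Hochberg values over all 17380 genes, with a threshold of 0.05. CPM values are TMM-scaled. Folds are log2 values with standard errors. The comparisons were synuclein against saline at each time, 12 against 7 weeks in each treatment, and the difference of the synuclein effect between the times. These 5 comparisons, 32 gene lists with 643 entries, the alternatives and the rule for naming genes were fixed before the data were examined. Of the entries, 626 matched the tables, and 31 lists had at least 3 members tested. A contrast of 12 against 7 weeks averaged over both treatments, and of synuclein against saline averaged over both times, were added after the results of the separate comparisons had been seen.

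Gene lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and with the correlation estimated, and with fry, both one-way (members moving one way on balance) and mixed (members changing in either direction), neither of which compares a list with other genes. The preset value treats the members of a list almost as independent genes. A library richer in 1 cell type moves all markers of that type together, so the estimated correlation is given beside each list call. List scores are means of log2 CPM with a prior count of 2. Score differences were tested by exact permutation within strata. The rule named the 12 genes with the smallest adjusted p under 0.05 in each direction among genes whose groups did not overlap, then 9 dopaminergic genes, then up to 4 members per list. Those list members were the called ones with the largest change or otherwise those with the highest mean expression. The rule was to leave out unnamed models, small RNAs and merged models, but only small RNAs were filtered, and only among the 12 genes in each direction. Some genes given below, such as Ddc and B2m, share their locus with other genes in the deposited files. The text does not give every gene the rule names.

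The procedure was tested on simulated counts drawn for the 17380 genes with 200 changed genes. A gene counted as recovered at an adjusted p under 0.05. For synuclein against saline at 7 weeks, edgeR recovered 9% of genes changed 2-fold, 47.8% of those changed 4-fold and 68.2% of those changed 8-fold, with 6 false calls, and DESeq2 1.42.0 made 46 false calls. At 12 weeks edgeR recovered 7.5%, 40.3% and 56.1%, with 1 false call, and DESeq2 made 34. For the difference between the times edgeR recovered 1.5%, 22.4% and 40.9% with 2 false calls (DESeq2 13), for 12 against 7 weeks in saline 6%, 47.8% and 65.2% with 4 (DESeq2 28), and in synuclein 6%, 46.3% and 63.6% with 1 (DESeq2 17). For 12 against 7 weeks over both treatments, edgeR recovered 19.4%, 64.2% and 87.9%, with 7 false calls, and DESeq2 made 28. These shares are over genes of all expression levels. Among changed genes above 20 CPM, edgeR recovered 15.4%, 81.6% and 97.3% for synuclein at 7 weeks and 13.9%, 68.4% and 86.7% at 12 weeks. For the difference between the times these were 3.1%, 44.1% and 83.3%. A simulated list of 20 genes raised 1.5-fold gave camera p-values from 7.6e-09 to 0.033 in 5 comparisons and 0.089 for the difference between the times, and lists of unchanged genes 0.34 to 0.86. The simulated genes varied independently of each other. The simulation therefore cannot show how many false calls of genes or lists arise where genes move together within a library. Other settings chosen at the outset were DESeq2 size factors, DESeq2's Wald test, limma-voom, no filter on low counts, only the groups compared, the replicate number as a block, each library left out in turn, and limma on log2(FPKM + 1). A pseudocount of 0.1, the recovered fragments, the authors' scaling alone, library weights, omission of 2 libraries that stand apart, omission of small RNAs and the dopaminergic score as a covariate were added after the data were seen. Settings meant for tables of group values had no use, since the tables hold values per sample.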

Results

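The series asked how gene expression in midbrain dopaminergic neurons differs 7 and 12 weeks after fibrils of G51D α-synuclein were injected next to them, an early stage of a Parkinson's disease model. Each of the 4 groups (saline and synuclein at 7 and at 12 weeks) held 3 libraries. Saline libraries at 7 weeks held 3299102, 3679181 and 5533321 assigned fragments, and synuclein libraries 3156346, 4462261 and 2506730. At 12 weeks the saline libraries held 2850322, 2590176 and 3915762 and the synuclein libraries 3421430, 5022488 and 4214154. Replicate 2 of synuclein at 12 weeks had 17409 genes with at least 1 fragment, against 19960 to 21135 in the other libraries, and lay apart on the first principal component (170.5, with 27.9% of the variance). Replicate 1 of the same group lay apart on the second component (−100.5, with 13.5%).

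The sorted material held RNA of dopaminergic neurons together with that of other cell types. Th, the rate-limiting enzyme of dopamine synthesis (chromosome 7, 142892776 to 142899966), ranged over the libraries from 160.5 to 857.6 CPM. Slc6a3, the dopamine transporter (chromosome 13, 73536747 to 73578672), ranged from 91.68 to 637.8 CPM. Mbp, the myelin basic protein of oligodendrocytes, ranged from 3364 to 10740 CPM, and Ly6c1, high in brain endothelium, from 2215 to 6504 CPM. Summed over the lists at 7 weeks in saline, oligodendrocyte markers made up 24340 ± 6080 CPM, endothelial markers 20220 ± 5560 and dopaminergic genes 2184 ± 601 (SD, n = 3).

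The first comparison asked what the fibrils changed after 7 weeks, and the dopaminergic genes varied more between libraries than between the treatments. They summed to 3356, 2000 and 1009 CPM after synuclein and to 2869, 1936 and 1747 after saline. Th was at 531 ± 313 CPM after synuclein and 530 ± 175 after saline, a log2 fold change of 0 ± 0.38 (SE). Slc6a3 was at −0.12 ± 0.42 and Slc18a2, the vesicular monoamine transporter, at 0.01 ± 0.45. Over 24 dopaminergic genes the median was 0.01, with 13 members higher and 11 lower. Over 26 other settings the folds ranged from −0.53 to 0.35 for Th, −0.70 to 0.26 for Slc6a3 and −0.56 to 0.54 for Slc18a2. Microglia markers had a median of 1.04, with 16 of 18 members higher after synuclein. Among them, C1qb of complement was at 1.48 ± 0.60 and the lysosomal protease Ctss at 1.19 ± 0.54, neither past the test over all genes (edgeR adjusted p = 1 for both). Replicate 3 of synuclein held much of that RNA, with 781.4 CPM summed over the list against 155.2 to 299.7 in the other libraries at 7 weeks.

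Lists of translation and protein folding lay slightly lower after synuclein at 7 weeks. Ribosomal protein genes had a median of −0.19, with 48 of 51 lower, and nuclear respiratory chain genes −0.16, with 44 of 50 lower. Proteasome subunits were at −0.17 with 25 of 31 lower, and heat-shock genes at −0.31 with 15 of 17 lower, including Hsp90aa1, a chaperone of many signalling proteins, at −0.60 ± 0.32. Replicate 3 of saline, the library with the most fragments (5533321), was highest of the 12 for 17 of 51 ribosomal and 23 of 50 respiratory chain genes. The same held for 16 of 31 proteasome and 0 of 17 heat-shock genes. Whether depth shifts such lists was not tested. Camera with the preset correlation gave adjusted p = 7e-07 for ribosomal proteins, 0.00016 for the respiratory chain, 0.0022 for the proteasome, 0.0041 for heat shock and 3.9e-05 for microglia. With an estimated correlation the adjusted p was 0.51 for the first 4 of these lists and 0.42 for microglia. The endoplasmic reticulum stress list was at −0.19 (preset 0.0032, estimated adjusted p = 0.41), endothelial markers at −0.27 (0.0032 and estimated adjusted p = 0.51) and antioxidant genes at −0.12 (0.013 and estimated adjusted p = 0.41). Astrocyte markers were at 0.55 (0.03 and estimated adjusted p = 0.51) and macrophage markers at 0.50 (0.016 and estimated adjusted p = 0.41).

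No gene passed the threshold at 7 weeks: edgeR called 0 of 17380 genes, and limma-voom and DESeq2 also called 0. At an unadjusted p under 0.05 edgeR had 285 genes, where evenly spread p-values would give 869. Other groupings of the same 7-week libraries gave 285 to 1015, so 869 is not the chance level of these data. Fry, a rotation test of each list, called 0 of 31 one-way and 0 mixed. Adjusted over the list alone, 0 members of the microglia list and 0 of the dopaminergic list passed. Without replicate 3 of synuclein the preset calls ended for microglia (median 0.27, adjusted p = 0.37), heat shock (−0.09, 0.15), respiratory chain (−0.09, 0.06), proteasome (−0.11, 0.069), antioxidant (−0.17, 0.069), astrocyte (0.19, 0.68) and macrophage lists (0.64, 0.06), and without replicate 3 of saline for ribosomal (−0.08, 0.12), respiratory chain (−0.07, 0.46), proteasome (0.04, 0.85), antioxidant (−0.06, 0.48), astrocyte (0.30, 0.46), macrophage (0.42, 0.13) and endothelial lists (−0.02, 0.61). Without replicate 2 of saline they ended for heat shock (−0.17, 0.069), endoplasmic reticulum stress (−0.18, 0.08) and macrophage (0.63, 0.1), and without replicate 1 of synuclein for endothelial (−0.15, 0.18) and macrophage (0.18, 0.19).

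The second comparison asked the same after 12 weeks, and heat-shock genes lay higher after synuclein. They had a median of 0.69, with 16 of 17 members higher and 8 of them at an unadjusted p under 0.05. Hspa8, a constitutive chaperone (chromosome 9, 40801273 to 40805199), was at 2690 ± 1120 CPM against 1670 ± 80.6 after saline, a fold of 0.69 ± 0.28 (edgeR adjusted p = 0.89). Hsp90ab1 was at 0.61 ± 0.31 and Hsp90aa1 at 0.53 ± 0.32. Adjusted over the list alone, 3 members passed, against 0 over all genes tested. Camera gave adjusted p = 1.6e-08 with the preset correlation, and adjusted p = 0.39 with an estimated correlation. Of the 17 members, 12 were highest of all 12 libraries in replicate 1 of synuclein, where the list summed to 12060 CPM against 5466 and 7296 in the other libraries of the group. That library also held the most ependymal RNA, 512 CPM summed over 7 markers.

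Dopaminergic genes had a median of 0.04, with 13 of 24 higher. Th was at −0.25 ± 0.38 (−0.44 to 0.09 over 26 other settings), Slc6a3 at −0.50 ± 0.42 (−0.74 to 0.02) and Slc18a2 at −0.18 ± 0.46 (−0.45 to 0.52). Drd2, the dopamine autoreceptor of these neurons, was at −1.34 ± 0.74 (edgeR adjusted p = 0.90). Microglia markers were at a median of −0.90, the opposite sign to 7 weeks, with 14 of 18 lower (preset adjusted p = 0.0061, estimated adjusted p = 0.93). Interferon genes were at 0.22 (0.0078 and estimated adjusted p = 0.93), with the class I antigen genes H2-D1 at 0.59 ± 0.36 and B2m at 0.54 ± 0.31. The p53 and apoptosis list was at 0.37 (0.0061 and estimated adjusted p = 0.14), with 22 of 25 higher, among them Bcl2l1, a survival gene, at 0.57 ± 0.25. Ribosomal proteins were at 0.13 (0.0087 and estimated adjusted p = 0.93), endothelial markers at 0.29 (0.009 and estimated adjusted p = 0.93) and immediate early genes at 0.26 (0.042 and estimated adjusted p = 0.39).

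At 12 weeks edgeR called 0 of 17380 genes, with 968 at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 called 12, of which 3 were higher. Fry called 0 of 31 lists one-way and 0 mixed. Without replicate 1 of synuclein the heat-shock median was 0.31 and stayed called with the preset correlation. Without both synuclein libraries that lie apart it was 0.08 and the call was lost (adjusted p = 0.14), as were those of microglia (−0.13, adjusted p = 0.83), ribosomal (0.14, 0.087) and immediate early lists (0.31, 0.16). The microglia call also ended without replicate 3 of saline (−0.22, adjusted p = 0.18) or replicate 1 of synuclein (−0.61, 0.19), and the ribosomal call without replicate 2 of synuclein (0.01, 0.96) or replicate 1 of saline (0.06, 0.094). Endothelial and interferon calls ended without replicate 1 of saline (0.18, 0.22; 0.03, 0.43) or replicate 3 of synuclein (0.14, 0.28; 0.13, 0.28), and the endothelial call also without replicate 2 of synuclein (0.24, 0.17). The immediate early call ended with limma-voom (0.22, adjusted p = 0.061). It also ended without replicate 2 of saline at 7 weeks (0.30, 0.053), replicates 1 (0.28, 0.11) or 2 (0.41, 0.079) of saline at 12 weeks, and replicates 1 (0.40, 0.19) or 3 (0.41, 0.17) of synuclein at 12 weeks.

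The difference of the synuclein effect between 12 and 7 weeks was tested as an interaction. Heat-shock genes had a median difference of 1.07, with 16 of 17 above 0, and microglia markers −1.73, with 18 of 18 below 0. Hsp90aa1 differed by 1.13 ± 0.46, Hspa5, a chaperone of the endoplasmic reticulum, by 1.35 ± 0.41, and C1qb by −2.11 ± 0.86 (edgeR adjusted p = 0.95 for each). Camera with the preset correlation gave adjusted p = 2.2e-09 for heat shock and 1.6e-06 for microglia, and with an estimated correlation adjusted p = 0.21 and 0.48. Over 25 other settings the medians ranged from 0.46 (without both synuclein libraries at 12 weeks that lie apart) to 1.29 for heat shock, and from −2.42 to −1.13 (without replicate 3 of synuclein at 7 weeks) for microglia, all called with the preset correlation. Fry called 0 of 31 lists one-way and 0 mixed. EdgeR called 0 genes, with 780 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The dopaminergic median was −0.06.

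The change with time in the saline group asked what differs without fibrils. Myelin genes lay higher at 12 weeks: 15 of 15 oligodendrocyte markers, with a median of 1.02, and 14 at an unadjusted p under 0.05. Mbp, myelin basic protein, was at 1.24 ± 0.24, Cnp at 1.06 ± 0.28 and Trf, the iron carrier transferrin, at 1.04 ± 0.30. Dopaminergic genes were at a median of −0.68 with 18 of 24 lower, among them Th at −1.16 ± 0.39 and Gch1, which makes a cofactor of Th, at −1.13 ± 0.31. Synaptic vesicle genes were at −0.60 with 28 of 33 lower, and Snap25, a fusion protein of the presynaptic terminal, at −1.82 ± 0.33. Adjusted over the list alone, 14 oligodendrocyte and 6 dopaminergic members passed. Ependymal markers were at 3.20 with 7 of 7 higher, and endothelial markers at −0.60 with 12 of 12 lower.

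EdgeR called 0 genes in saline, with 1289 at an unadjusted p under 0.05 and 10 at an adjusted p under 0.1, among them Sox10 at 1.97 ± 0.36, Galnt6 at 2.02 ± 0.35 and Snap25 (edgeR adjusted p = 0.0886 for each), named after their values were seen. Limma-voom called 0 and DESeq2 165. Camera's preset adjusted p was 3.4e-18 for oligodendrocyte, 9.1e-08 for dopaminergic and for synaptic vesicle genes, 1.4e-07 for endothelial, and 2.5e-05 for ependymal markers. With an estimated correlation these were adjusted p = 0.22, 0.36, 0.36, 0.36 and 0.36. Over 25 other settings the medians ranged from 0.77 to 1.28 for oligodendrocyte, −1.31 to −0.44 for dopaminergic, −0.73 to −0.48 for synaptic vesicle, −0.80 to −0.33 for endothelial and 1.91 to 4.02 for ependymal lists, all called with the preset correlation. The p53 and apoptosis list was the 1 list called both ways: its genes fell as a set, with a median of −0.44 and 23 of 25 lower (preset adjusted p = 8.5e-06, estimated adjusted p = 0.021). It was also the 1 list called by fry one-way (adjusted p = 0.013), while fry's mixed test, of members moving either way, called 4: p53, axon injury, immediate early and oligodendrocyte precursor genes. Bcl2l1 was at −1.12 ± 0.26 and Cdkn1a, a cell cycle inhibitor, at −1.59 ± 0.64. Heat-shock genes were at −0.49 (7.9e-05, estimated adjusted p = 0.37), the respiratory chain at −0.23 (1.7e-05, estimated adjusted p = 0.66) and immediate early genes at −0.59 (0.003, estimated adjusted p = 0.20). Cdkn1a stood at 656.8 CPM in replicate 1 of saline at 7 weeks, against at most 350.9 in the other libraries. The Cdkn1a fold ranged from −2.14 to −0.63 over 25 other settings.

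The same change in the synuclein group had the same sign as in saline for oligodendrocyte, dopaminergic and synaptic vesicle lists. Oligodendrocyte markers were at 0.77 with 15 of 15 higher, dopaminergic genes at −0.77 with 20 of 24 lower, and synaptic vesicle genes at −0.69 with 31 of 33 lower. Th was at −1.41 ± 0.39, Slc6a3 at −1.45 ± 0.43, Mbp at 0.95 ± 0.23 and Snap25 at −0.98 ± 0.32. Microglia markers were at −1.53 with 18 of 18 lower, and heat-shock genes at 0.43 with 16 of 17 higher, where saline had medians of 0.12 (preset adjusted p = 0.55) and −0.49. These differences between the treatments are the interaction given above. Endothelial markers were at −0.02 (preset adjusted p = 0.92). Ribosomal proteins were at 0.22 (preset adjusted p = 2.1e-05), the opposite sign to saline (−0.12, 0.039). Macrophage markers were at −1.29 (0.0033) and ependymal markers at 2.82 (0.0067). The ependymal call held in 19 of 25 other settings, with medians from −0.19 to 3.36. With an estimated correlation 0 of 31 lists were called in synuclein. Camera's preset adjusted p was 2.9e-15, 3.7e-06, 5.5e-07, 1.5e-07 and 0.00015 for the oligodendrocyte, dopaminergic, synaptic vesicle, microglia and heat-shock lists, and with an estimated correlation adjusted p = 0.49 for each. Fry called 0 of 31 lists one-way and 2 mixed, the axon injury and immediate early lists. EdgeR called 0 genes, with 1318 at an unadjusted p under 0.05, limma-voom 0 and DESeq2 82. Without replicate 1 of synuclein at 12 weeks the heat-shock call was lost (median 0.12, adjusted p = 0.33; −0.12 and 0.96 without both libraries that lie apart), and without replicate 1 of synuclein at 7 weeks that of synaptic vesicle genes (−0.26, 0.061). Without that 7-week library the dopaminergic median was −0.32, and without replicate 3 of synuclein at 7 weeks the microglia median was −0.70, both still called with the preset correlation.

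**Figure D1:**
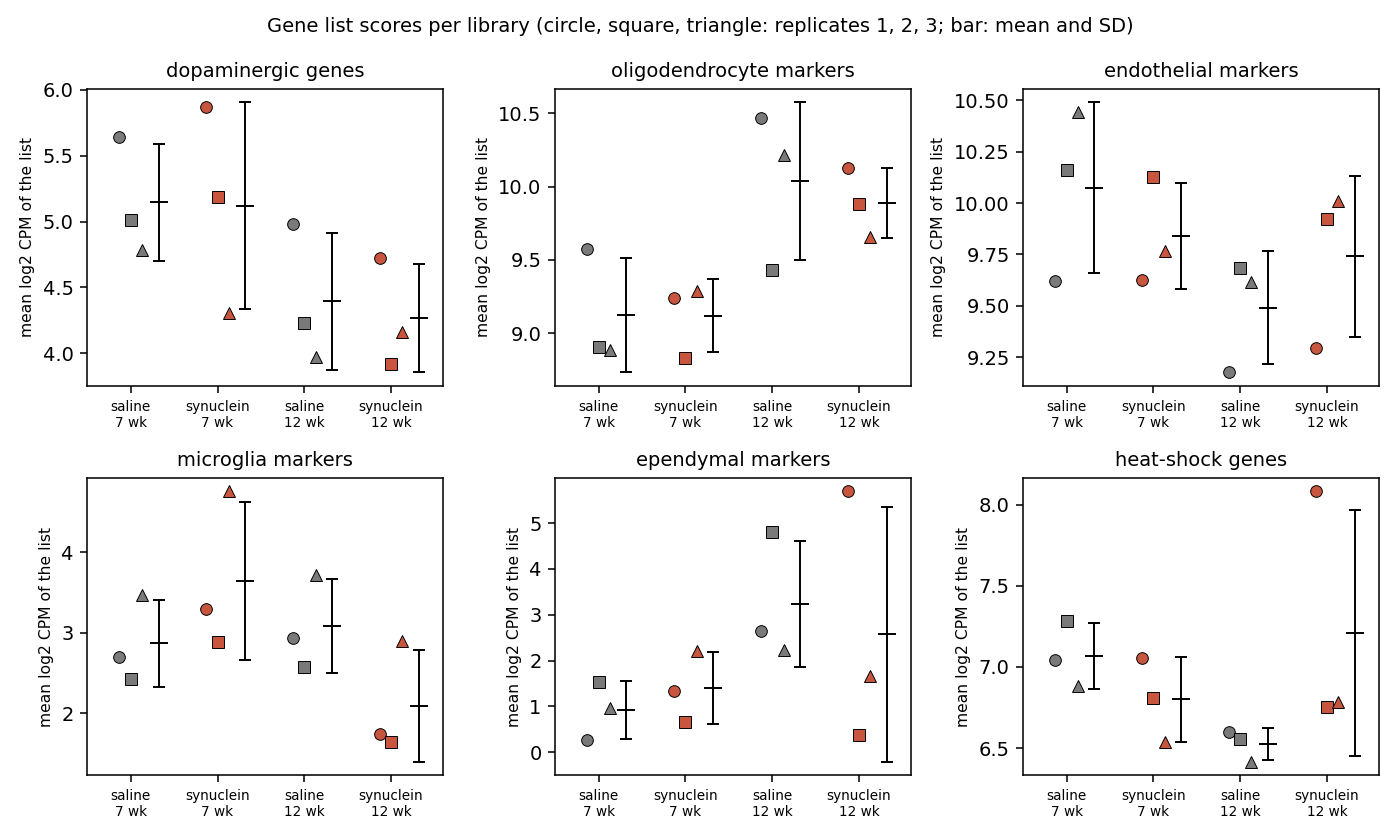
Mean log2 CPM of 6 gene lists (vertical axes, which do not start at 0) in the 12 libraries by group, with points for replicates and bars for the mean and SD of 3 libraries. On average, oligodendrocyte scores lie higher and dopaminergic scores lower at 12 weeks, while dopaminergic scores overlap between the times. The highest microglia (4.758) and heat-shock (8.081) scores each come from 1 synuclein library.

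Because the separate time comparisons pointed the same way, 12 against 7 weeks was also tested over both treatments, with 6 libraries at each time. Some genes of myelin rose from 7 to 12 weeks. Mbp (chromosome 18, 82475123 to 82585637) went from 3890 ± 460 to 9150 ± 1390 CPM in saline and from 4190 ± 814 to 8080 ± 1570 in synuclein (SD, n = 3), a fold of 1.09 ± 0.17 (edgeR adjusted p = 0.016). Sox10 and Myrf, transcription factors of the oligodendrocyte lineage and of myelination, rose by 1.62 ± 0.25 and 1.37 ± 0.22, and Cntn2, an adhesion protein of myelinated axons, by 1.21 ± 0.20 (edgeR adjusted p = 0.016 for each). Of 15 oligodendrocyte markers, 7 rose over all genes tested and 15 adjusted over the list alone, with a median of 0.87.

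Of 24 dopaminergic and 33 synaptic vesicle genes, 4 and 5 fell over the same interval by the test over all genes. Th fell by 1.29 ± 0.27 on the log2 scale, Slc18a2 (chromosome 19, 59260878 to 59296012) fell by 1.45 ± 0.33, Calb1, a calcium buffer, fell by 1.40 ± 0.29, and Chrna6, a nicotinic receptor subunit of these neurons, fell by 1.87 ± 0.36 (edgeR adjusted p = 0.038, 0.047, 0.038 and 0.026). These were the 4 of 24 dopaminergic genes called over all genes, against 10 adjusted over the list alone, and the median was −0.83. Slc6a3 was at −1.26 ± 0.30 (edgeR adjusted p = 0.057), Nr4a2, a transcription factor that maintains these neurons, at −1.19 ± 0.32 (0.095), Aldh1a1 at −1.24 ± 0.37 (0.14), Drd2 at −1.42 ± 0.51 (0.28), Pitx3 at −1.38 ± 0.78 (0.63) and Ddc, the last enzyme of dopamine synthesis, at −0.47 ± 0.25 (0.57). Of 33 synaptic vesicle genes, 5 fell over all genes and 12 adjusted over the list alone, among them Snap25, which fell by 1.40 ± 0.23, and Rab3c, which fell by 1.28 ± 0.27. Camera's preset adjusted p was 4.1e-28 for oligodendrocyte, 2.9e-11 for dopaminergic and 4.9e-12 for synaptic vesicle genes. With an estimated correlation these were adjusted p = 0.13, 0.35 and 0.35, and by exact permutation of the list scores adjusted p = 0.12, 0.19 and 0.12. Ependymal markers were at 2.61 with 7 of 7 higher (4.7e-06, estimated adjusted p = 0.35), mostly from 512 and 256.2 CPM summed over the list in replicate 1 of synuclein and replicate 2 of saline at 12 weeks, and endothelial markers at −0.29 with 12 of 12 lower (0.0014, estimated adjusted p = 0.46). The p53 and apoptosis list was at −0.29 with 19 of 25 lower (0.0058, estimated adjusted p = 0.13) and the 1 list called by fry one-way (adjusted p = 0.042), and Bcl2l1 fell by 0.82 ± 0.18. That fall was larger in saline, where the mean p53 score went from 5.34 to 4.82, than in synuclein, where it went from 5.24 to 5.08. Bcl2l1 was at −1.12 ± 0.26 in saline and −0.52 ± 0.25 in synuclein. Fry's mixed test called 10 lists, among them the dopaminergic, synaptic vesicle and oligodendrocyte lists.

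Among markers of other cell types, scores changed by 0.01 for astrocytes, −0.04 for mural cells and 0.42 for fibroblasts from 7 to 12 weeks over both treatments. Microglia, macrophage and serotonergic lists were called lower with the preset correlation but not in every setting. Microglia markers were at −0.78 with 16 of 18 lower (preset adjusted p = 0.003, estimated adjusted p = 0.46), and the call ended without replicate 3 of synuclein at 7 weeks (−0.37, 0.13). Their median was −1.53 in synuclein and 0.12 in saline. Serotonergic and noradrenergic markers were at −0.95 with 7 of 7 lower (0.03, estimated adjusted p = 0.39). That call ended without replicate 1 of saline (−0.55, 0.15) or of synuclein (−0.73, 0.11) at 7 weeks, or replicate 3 of synuclein at 12 weeks (−0.93, 0.12). Macrophage markers were at −0.57 (0.017, estimated adjusted p = 0.35), and their call ended without both synuclein libraries at 12 weeks that lie apart (−0.53, 0.088). The endothelial call ended without replicate 1 of synuclein at 12 weeks (−0.17, 0.081), and the endothelial median was −0.60 in saline and −0.02 in synuclein. Oligodendrocyte precursor markers were at 0.16 (0.04, estimated adjusted p = 0.35), called in 13 of 24 settings, and the respiratory chain at −0.15 (0.047, estimated adjusted p = 0.80), called in 10 of 24.

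Among the other leading genes, Nfix, a nuclear factor I transcription factor, rose by 1.35 ± 0.21, and Scd2, a fatty acid desaturase, by 1.04 ± 0.17. Galnt6 rose by 1.46 ± 0.24, Rassf2 by 1.70 ± 0.29, Aatk by 1.11 ± 0.19, Tmem88b by 1.10 ± 0.19, Ddr1, a collagen receptor, by 1.32 ± 0.23, and Plekhb1 by 1.05 ± 0.18. Gprasp2 fell by 1.58 ± 0.25, Atp6v1g2, a subunit of the vesicular proton pump, fell by 1.45 ± 0.23, and Ndn, a growth suppressor of neurons, fell by 1.35 ± 0.26. Zcchc12 fell by 1.51 ± 0.28, Cck, a neuropeptide of midbrain dopaminergic neurons, fell by 1.34 ± 0.27, Napb, which helps recycle fusion complexes, fell by 1.32 ± 0.27, and Stmn2, a regulator of microtubules in axons, fell by 1.04 ± 0.22. Sult1a1, Fam107a, Rgcc, Zwint and Tagln3 were called lower as well, at −1.61, −1.43, −1.07, −1.31 and −1.51. C4b of complement rose by 1.43 ± 0.30 and Arc, an activity-regulated gene, by 1.29 ± 0.27. Atp13a2, a lysosomal transporter mutated in a familial parkinsonism, fell by 0.98 ± 0.22 (edgeR adjusted p = 0.045). Rpl26 and Gm5512 were also called lower, but Rpl26 is listed at 0 CPM in all 3 saline libraries at 12 weeks and Gm5512 in 2 of them, so no fold is given.

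EdgeR called 145 genes in this contrast, 94 higher and 51 lower at 12 weeks, with 1707 at an unadjusted p under 0.05. Limma-voom called 133 and DESeq2 468. Calls numbered 24 without replicate 3 and 32 without replicate 2 of saline at 7 weeks, 28 and 38 without replicates 1 and 2 of synuclein at 7 weeks, 27 and 29 without replicates 1 and 3 of saline at 12 weeks, and 38 without replicate 1 of synuclein at 12 weeks. They numbered 0 without both synuclein libraries at 12 weeks that lie apart, and Th was called in 11 of 24 settings and Mbp in 22. Limma on log2(FPKM + 1) called 5.

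**Figure D2:**
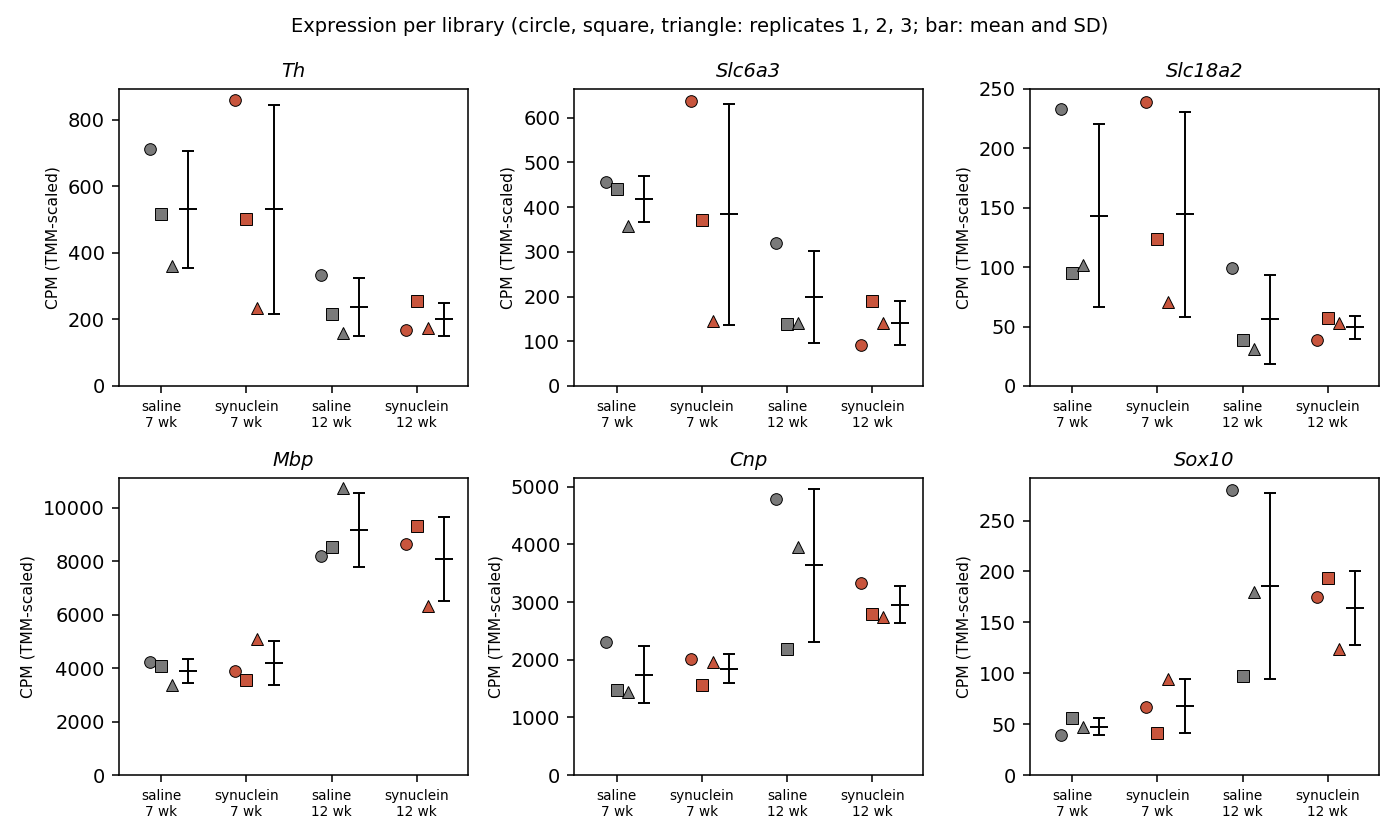
TMM-scaled CPM (linear axes from 0) of Th, Slc6a3, Slc18a2, Mbp, Cnp and Sox10 in the 12 libraries by group, with points for replicates and bars for the mean and SD of 3 libraries. Mbp lies between 3364 and 5106 CPM in all 7-week libraries and between 6307 and 10740 in all 12-week libraries, while Th overlaps between the times.

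**Figure D3:**
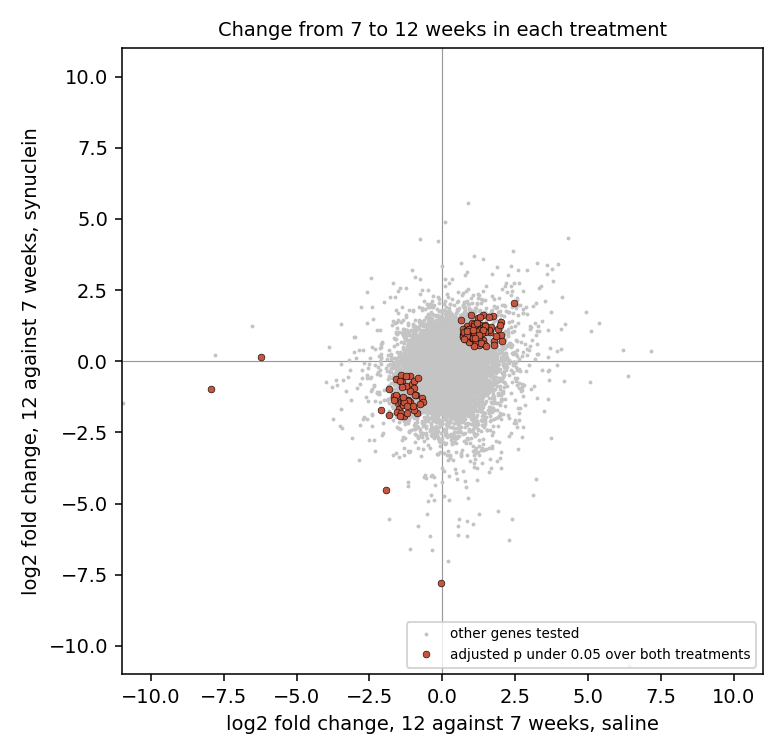
Log2 fold change from 7 to 12 weeks in saline (horizontal) and in synuclein (vertical) for the 17380 genes tested, with the 145 genes called over both treatments in red. The called genes lie in the lower left and upper right quadrants, all but Gm5512, and were chosen by the average of both axes.

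Averaged over both times, synuclein against saline gave 0 calls by edgeR, with 431 genes at an unadjusted p under 0.05, 0 by limma-voom and 3 by DESeq2. The smallest adjusted p was 0.48. Heat-shock genes were the 1 list called with the preset correlation (median 0.24, adjusted p = 0.022, estimated adjusted p = 0.93), in 16 of 25 other settings, and fry called 0 of 31 one-way and 0 mixed.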

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

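The tests of explanations below were chosen after the results were seen, while the counts over other splits of the samples were chosen before their results were seen. The synuclein effect differed between 12 and 7 weeks, by the interaction with the preset correlation, for 10 gene lists. The median difference was 1.07 for heat shock (camera adjusted p = 2.2e-09; adjusted p = 0.21 with an estimated correlation), −1.73 for microglia (1.6e-06; 0.48), 0.33 for ribosomal proteins (7.3e-07; 0.76) and 0.55 for endothelial markers (0.00015; 0.76). It was 0.26 for the respiratory chain (0.00015; 0.76), 0.38 for endoplasmic reticulum stress (0.0013; 0.18), 0.38 for p53 and apoptosis (0.0014; 0.12) and 0.21 for the proteasome (0.0019; 0.76). It was 0.54 for immediate early genes (0.0092; 0.18) and 0.23 for interferon genes (0.021; 0.76). None of the 10 held with an estimated correlation. Of 51 ribosomal protein genes, 29 were highest of the 12 libraries in replicate 2 of synuclein at 12 weeks and 17 in replicate 3 of saline at 7 weeks. These libraries had the most fragments (5022488 and 5533321), and an effect of depth was not tested. Without replicate 3 of saline at 7 weeks the proteasome call ended (0.05, adjusted p = 0.17), and without replicate 3 of synuclein at 7 weeks that of immediate early genes (0.42, 0.078). The interferon call ended without replicate 2 (0.31, 0.19) or 3 (0.19, 0.057) of saline at 7 weeks, replicate 1 of saline at 12 weeks (0.02, 0.41) or replicate 3 of synuclein at 12 weeks (0.12, 0.23), and was held in 19 of 25 settings.

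Chance cannot be excluded for the difference between the times: of 100 splits, 31 gave as many genes at an unadjusted p under 0.05 (780, highest other 2178) and 28 as many lists (10, highest other 15). The same holds for synuclein against saline over both times, with 98 of 100 splits for genes (431, highest other 2178) and 100 of 100 for lists (1, highest other 15). The highest count of genes came from the same grouping of the libraries in both cases. It called 97 genes where the real one called 0. That grouping set the libraries with fewer fragments at each time apart from those with more. At 7 weeks they held 2506730 to 3299102 fragments against 3679181 to 5533321. At 12 weeks they held 2590176 to 3421430 against 3915762 to 5022488. The same grouping put replicate 1 of every group on the side with fewer fragments. Depth was looked at only after this split had given the highest count. The count therefore points to a structure other than treatment. Library depth, replicate number and cell content cannot be told apart as its source, and its cause was not tested. With 10 splits, too few for a share under 0.05, the counts at 7 weeks were reached by 10 for genes (285, highest other 1015) and 7 for lists (10, highest other 16). At 12 weeks they were reached by 4 (968, highest other 1455) and 2 (7, highest other 7). In saline they were reached by 1 (1289, highest other 963) and 2 (12, highest other 13), and in synuclein by 2 (1318, highest other 1445) and 7 (8, highest other 13), again of 10. For 12 against 7 weeks over both treatments, only the real split of 100 reached its count of genes called (145, highest other 11). For the lists 24 of 100 did (11, highest other 15). By genes at an unadjusted p under 0.05, another split gave more than the real one (1771 against 1707). The contrast was added after the separate results were seen, which the splits do not allow for. Chance is therefore argued against for the count of genes called, but not excluded, and it stays open for the lists.

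Oligodendrocyte markers were higher and dopaminergic genes lower at 12 than at 7 weeks, in both treatments. A lower share of sorted neurons would raise the markers of every other cell type alike, but the oligodendrocyte score changed by 1.18 log2 more than the endothelial score (2-sided exact permutation p = 0.02, 6 against 6, adjusted p = 0.048 over 8 other cell types), which argues against that alone, although mural (0.88, adjusted p = 0.087), fibroblast (0.42, 0.22) and ependymal scores (−0.90, 0.38) were not told apart from it. A larger share of oligodendrocyte RNA could lower the dopaminergic genes by dilution, which would lower every other type alike, and the dopaminergic score changed by −0.90 relative to the mean of 8 other types (exact permutation p = 0.055). Relative to single types it changed by −0.81 for astrocytes (adjusted p = 0.15), −1.04 for oligodendrocyte precursors, −1.22 for fibroblasts and −2.54 for ependymal cells (0.08 for each). It changed by −0.76 for mural cells (0.37), −0.46 for endothelium (0.45), −0.25 for macrophages (0.51) and −0.13 for microglia (0.86). None of the 8 passed 0.05 after adjustment. The ependymal rise came mostly from replicate 1 of synuclein and replicate 2 of saline at 12 weeks. Dilution therefore cannot be told apart from a fall within the neurons. Time after injection, age, and the sorting or library batch, which the labels do not give, stay open as untested.

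Heat-shock genes were higher after synuclein at 12 weeks. Of 17 members, 12 were highest of the 12 libraries in replicate 1 of synuclein, so a response of that library is a candidate explanation for most of the difference. A dissociation response with immediate early genes stays open, since their score there lay 0.28 above the mean of the other 5 libraries at 12 weeks (SD 0.09), and an earlier test by rank over both times (6 of 12) was dropped because the 5 higher libraries were all from 7 weeks. Ependymal RNA in the same library stays open: replicate 2 of saline, the only other library rich in it, had a heat-shock score −0.24 from the median of 10 other libraries where its share would give 0.78, but 1 library excludes nothing. An effect of the fibrils in that library stays open too.

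Microglia markers were higher after synuclein at 7 weeks. Of 18 members, 13 were highest of the 12 libraries in replicate 3 of synuclein, so RNA in that 1 library may account for most of the difference. The microglia excess of that library (1.8) passed its endothelial excess (−0.23) by 2.03, with an SD of 0.51 among the other 5 libraries. This does not decide whether a lower share of sorted neurons raised all other types alike. The library was singled out by its microglia values, and the result depends on endothelium as the reference. The change was wider than microglia, since mural (1.86), ependymal (1.26), fibroblast (1.05), astrocyte (0.79) and oligodendrocyte precursor (0.76) scores were higher there too and the dopaminergic score lower (−1). A lower share of neurons as the whole or a part of the change therefore stays open, as does whether the fibrils or the sort brought that RNA.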

How the results depend on the processing

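Tests with an FPKM pseudocount of 0.1, library weights or omission of 2 libraries, and all settings of the averaged contrasts, were chosen after the results were seen. DESeq2's Wald test called 12 genes for synuclein at 12 weeks, 165 for time in saline, 82 for time in synuclein, 468 for time over both treatments and 3 for synuclein over both times, and made more false calls than edgeR on simulated data. For time in saline, no filter gave 7, only the 2 groups compared 49 and library weights 54. Limma on log2(FPKM + 1) gave 1 for synuclein at 12 weeks, 1 for the difference between times, 1 for time in saline and 5 for time over both treatments, and with a pseudocount of 0.1, 2, 1, 2 and 1, and 1 for synuclein over both times. Without both synuclein libraries at 12 weeks that lie apart, time in saline gave 14 and time over both treatments 0 (smallest adjusted p = 0.13). Over the 5 comparisons fixed at the outset, 47 list calls with the preset correlation became 1 with an estimated one. The cause of these differences was not tested.

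Leaving out 1 library gave 0 to 1 calls for synuclein at 7 weeks, 0 to 1 at 12 weeks, 0 for the difference between times, 0 to 9 for time in saline, 0 to 2 for time in synuclein, 24 to 214 for time over both treatments, 0 to 1 for synuclein over both times and 45 to 63 for lists. For time over both treatments, DESeq2 size factors gave 159, limma-voom 133, no filter 200, the recovered fragments 142, the authors' scaling 156, library weights 165 and omission of small RNAs 158. Oligodendrocyte, dopaminergic, synaptic vesicle, ependymal and p53 lists were called there in 24 of 24 settings, all with the preset correlation, with dopaminergic medians from −1.25 to −0.70. With an estimated correlation 0 of 31 lists were called there (smallest camera adjusted p = 0.13).

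The replicate number as a block gave 36 calls for time in saline and 258 for time over both treatments, and 0 for the other comparisons. Same-numbered samples had correlations of deviations from −0.06 to 0.11, and 5 of 12 samples correlated best with their own number, so the numbers are not taken as a pairing. Replicate 1 had the highest dopaminergic score in 4 of 4 groups (exact permutation p = 0.014, adjusted p = 0.22 over 31 lists) and the lowest endothelial score in 4 of 4 (0.037, adjusted p = 0.38). The smallest p was 0.0046 for microglia (adjusted p = 0.14), so a shared number is not excluded as a source of differences. Settings for tables of group values gave no value, and the 2 groups alone cannot give the difference between times.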

Other observations

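The test of a hypothesis in this part was chosen after the results were seen. Single libraries held much RNA of other cell types. Tph2, the serotonin-making enzyme of the raphe, stood at 503.6 CPM in replicate 1 of synuclein at 7 weeks, against 0.5667 to 152.2 in the others, and Slc6a4, the serotonin transporter, at 189.2. Acta2, of smooth muscle, stood at 469.1 CPM in replicate 3 of synuclein at 7 weeks, where mural markers summed to 1045 CPM against 150.5 to 347.2 in the others. Erythrocyte genes summed to 390.4 to 3016 CPM.

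Over both treatments, lists of lysosomal genes (median 0.01), autophagy genes (0.01) and genes of inherited Parkinson's disease (0.02) lay close to 0 from 7 to 12 weeks, with camera adjusted p = 0.27, 0.69 and 0.46. The dopaminergic score changed by −0.80 (exact permutation p = 0.03, adjusted p = 0.19 over 31 lists), and the synaptic vesicle score by −0.62 (0.005, the smallest the 400 relabelings can give, adjusted p = 0.12). A hypothesis that the dopaminergic genes fell beyond the synaptic vesicle genes was not decided by its test, with a difference of −0.18 (exact permutation p = 0.43). Relative to the mean of the ribosomal, proteasome and respiratory chain lists, the dopaminergic score changed by −0.76 (exact permutation p = 0.045). All cells express those genes, so a smaller share of neurons would also lower the score relative to them. The test therefore cannot tell a change in cell composition from a fall within the neurons.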
